A study of Mus musculus with 2 samples.

How the data were processed

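The data are from 2 libraries of cells from whole mouse brain tissue at postnatal day 10, a stage at which glia and some neurons are still being formed. Per the labels, both belong to 1 group, carry the replicate numbers 1 and 2, and come from the mouse strain given as C57BL/J. The series names 6 mice but does not tie any mouse to a library. Nothing says whether the libraries came from separate animals. The p-values thus measure only how much the differences between classes vary from 1 library to the other, which may be technical. Fresh suspensions were put through the droplet-based Chromium 3' v3 kit of 10x Genomics, which tags each captured messenger RNA molecule at its 3' end with a unique molecular identifier (UMI), and were sequenced on an MGISEQ-2000 to 700 M raw reads each, per the labels' protocols.

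The deposited values are counts: the authors' files give the number of UMIs per gene and cell barcode, with no normalisation, per the file headers and the values, which were whole numbers. They were made with Cell Ranger 6.1.2 on genome build mm10, per the submitters' processing notes. The annotation release and the settings of the cell calling are not given in the sources used here. The tables list 32285 features and hold 12978 barcodes with 51452085 UMIs in library 1 and 19508 barcodes with 45532691 UMIs in library 2. The lowest barcode held 500 UMIs in both, so barcodes under that number had been left out before deposition. Gene coordinates were taken from GENCODE release M21 on mm10, matched by gene identifier, with positions counted from 1. The kit keeps strand, but the counting settings of overlapping genes are not given in the sources used here, so antisense or overlapping transcripts such as Dlx1as and Sox1ot and members of multigene families such as Ccl3 and Ccl4, Ifi208 and Ifi211, Gimap5 and Slco1a4 are uncertain.

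Choices made before the data were examined were the quality limits, the clustering settings, 30 marker lists, 20 gene lists for testing, the tests and the rule for named genes. Barcodes were kept with at least 500 genes and at most 10% of UMIs from mitochondrial genes, which left 12618 in library 1 and 14965 in library 2. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 6%. In library 1 the automatic threshold marked 626 barcodes. In library 2 it marked 0, so the highest-scoring barcodes up to the expected rate were removed there, 844 in all, a choice made after seeing the data. After this 11992 and 14121 barcodes remained. Counts were scaled to 10000 per cell and log-transformed, the 2000 most variable genes were reduced to 30 principal components, and Leiden clustering was run at resolution 1 on 15 neighbours. The gene lists under test and ribosomal and mitochondrial genes were left out of the clustering genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and R 4.3.3 were used.

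Clusters were named "X-like" from the mean log2 ratio of each marker list to the other clusters, with at least 3 markers detected at 2-fold and 20 CPM (UMI counts scaled to a common total per sum). The scoring limits were set after seeing the data. So was the rule that a cluster stays unnamed if its UMI count is under 0.6 of the median of its libraries and over 95% of its cells come from 1 library. Of 27 clusters, 22 were named and merged into 14 classes. The largest microglia-like cluster was led by Gdf15, Cx3cr1, Ccl4, Ccl3, P2ry12 and Cxcl10, so stress and immune genes stood among its leading genes.

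UMIs were summed per library and class, and each sum was 1 value of its library, so n = 2. Sums were tested with the quasi-likelihood F test of edgeR 4.0.16 (TMM scaling, filterByExpr, Benjamini-Hochberg adjustment, two-sided). The model held the class and the library as a block, because the classes of 1 library come from the same suspension. All classes with at least 50 cells in both libraries, 10 in number, entered 1 fit and shared 1 estimate of the spread with 9 residual degrees of freedom. Clustering genes and markers were left out of the tested genes, since genes that define a class are no finding about it, which left 13347. The remaining genes still correlate with those used for clustering, so the tests describe the classes as drawn and their p-values are too small as evidence that the classes exist. A gene was called at an adjusted p under 0.05, a log2 fold change of at least 1 and the same sign in both libraries. Of 8 comparisons planned, 6 were run as planned. A class named oligodendrocyte-like was not found, so the class with markers of committed precursors and of oligodendrocytes together took its place, and border macrophage-like cells were too few for the limit of 50. Both comparisons were run in a second fit at 40 cells per library (13331 genes tested, 11 residual degrees of freedom), and a comparison of neuroblast-like with neural progenitor-like cells was added to the first fit. These 3 were chosen after seeing the data.

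Levels are mean CPM ± SD over the libraries. Fitted log2 fold changes are given ± their standard error, computed from the F statistic, and not ± SD. Folds are ratios of mean CPM. Where 1 side had no count, the fold was computed against a floor of 3 counts over the group and is a lower bound, and where it had 1 to 3 counts the ratio of pooled counts is given with an exact 95% counting interval, both on the TMM-scaled sizes. Fitted log2 fold changes of such genes depend on the prior count and are not given. In comparisons with the mean of the other classes, fitted values average logarithms, so they were pulled by classes with no counts, and CPM ratios are printed instead. Named genes were, in a class against the others, the 10 highest and 5 lowest called fold changes and, between classes, the 8 highest and 8 lowest. They had at least 20 CPM in both libraries on the higher side and a gene name. The 2 most changed called members of every called list were added.

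Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 20 lists within a comparison, and again with the correlation estimated from the data. They were cholesterol biosynthesis, glycolysis, oxidative phosphorylation, S phase, G2 and M phase, dissociation and immediate early genes, MHC class I presentation, interferon response, glutamate receptors, GABA receptors, sodium and potassium channels, basement membrane, blood-brain barrier transporters, glial synapse-forming and pruning factors, the axon tract microglia programme, lysosome, Notch pathway, Wnt pathway, growth factors and cytokines, and insulin, thyroid and steroid hormone response. Shares of cells carry exact 95% Clopper-Pearson intervals, which cover counting error only. For shares of cells with cell cycle genes, each cell was thinned to 2000 UMIs and shallower cells were left out.

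The test procedure was tested on simulated counts with 200 changed genes and no unchanged gene was called in any comparison. Each gene was drawn independently there, at a spread set by its expression level alone. Real genes are correlated and differ in spread, so this sets no bound on false calls in the real counts. In neuroblast-like against progenitor-like cells, run on 13105 genes, 7.5% of genes changed 2-fold, 70.1% changed 4-fold and 83.3% changed 8-fold were recovered. In border macrophage-like against microglia-like cells, run on 13062 genes, these were 0%, 29.9% and 54.5%. Alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no low-count filter, no library block, other quality limits, doublets kept, other clustering settings, all genes tested, a log2 threshold of 2 and leaving out each library. Added after seeing the data were a fit on the classes compared only, fits without clusters led by markers of another class, by Ttr, by histone genes or by Neurod1, a fit with fewer excitatory neuron-like cells, a G2 and M phase list without Tubb4b, and lists against all genes past the filter.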

Results

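Whole brains of mice at postnatal day 10 were profiled cell by cell in 2 libraries of 1 group, without a treatment or a control. Library 1 held 12978 barcodes with 51452085 UMIs and library 2 held 19508 barcodes with 45532691 UMIs. The median barcode had 3446 UMIs and 1580 genes in library 1 and 1470 UMIs and 800 genes in library 2. With at least 500 genes and at most 10% mitochondrial UMIs, 97.2% of barcodes passed in library 1 and 76.7% in library 2. After removal of doublets, 11992 and 14121 cells remained, with a median of 3426 and 1910 UMIs. Of these 11686 cells of library 1 and 9017 of library 2 fell into 14 named classes. Within a class, log2(CPM + 1) values of 13347 genes correlated between the libraries with a median Pearson r of 0.947 and Spearman rho of 0.945 over the classes. The lowest were 0.735 and 0.733, in fibroblast-like cells, of which library 2 held 8. These correlations are across genes, which are not independent replicates. The labels name no contrast, so the question was which cell types the tissue held and which genes set them apart.

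Neuroblast-like cells, the migrating young neurons, were on average the most frequent class, with 24.1% ± 3.55 of cells (SD, n = 2). A cluster of 984 and 1229 of them had 1 neuroblast and 2 inhibitory neuron markers among its 10 leading genes. Clusters with no marker of their own class among these 10 genes held 1187 and 898 neuroblast-like, 1316 and 565 neural progenitor-like and 970 and 650 excitatory neuron-like cells. No order is given for the classes that follow. Neural progenitor-like cells took 13.7% ± 8.81, but 6.41% at Leiden resolution 2 and 6.06% with 4000 variable genes. Astrocyte-like cells took 8.06% ± 4.52, but 4.49% at resolution 0.5 and 2, where 879 and 806 cells of their Ttr-led cluster were named choroid plexus epithelial-like (3.60% and 3.28% of cells). Only 9 cells of that class had UMIs of at least 3 choroid plexus markers besides Ttr. Oligodendrocyte precursor-like cells took 8.01% ± 5.53 and excitatory neuron-like cells 7.96% ± 2.92. Microglia-like cells, the resident macrophages of brain tissue, took 0.792% of cells in library 1 (exact Clopper-Pearson 95% interval 0.641 to 0.968) and 13.9% in library 2 (13.3 to 14.4), 17.5 times as much. Border macrophage-like cells, which sit in the meninges and around vessels, took 0.367% (0.267 to 0.492) and 1.19% (1.02 to 1.38). With stricter limits the means were 12.3% in place of 7.32% for microglia-like and 1.40% in place of 0.778% for border macrophage-like cells. In the other direction, pericyte-like cells took 4.43% (4.07 to 4.81) and 0.489% (0.380 to 0.618), ependymal-like cells 3.25% (2.94 to 3.59) and 0.368% (0.275 to 0.483), and differentiating oligodendrocyte-like cells 3.76% (3.43 to 4.12) and 0.312% (0.227 to 0.418), on average 2.04% but 1.10% at resolution 2. Endothelial-like cells took 0.926% (0.762 to 1.11) and 0.949% (0.796 to 1.12), over named cells alone 0.9499% and 1.49%, and with stricter quality limits 1.05% and 1.71%. Inhibitory neuron-like cells averaged 2.73% ± 0.986, but 0.767% to 1.62% with other quality limits or 4000 variable genes, Cajal-Retzius cell-like cells 0.508% ± 0.283 (1.05% with stricter limits) and fibroblast-like cells 0.266% ± 0.296. The intervals cover counting error only, and no test was made between libraries of 1 group. A rule set after seeing the data left out clusters of low UMI count. A globin-led cluster among them held 0.025% of cells in library 1 and 14.3% in library 2, and the other held 0.158% and 20.3%. Over named cells alone, microglia-like cells took 0.813% and 21.7%.

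**Figure D1:**
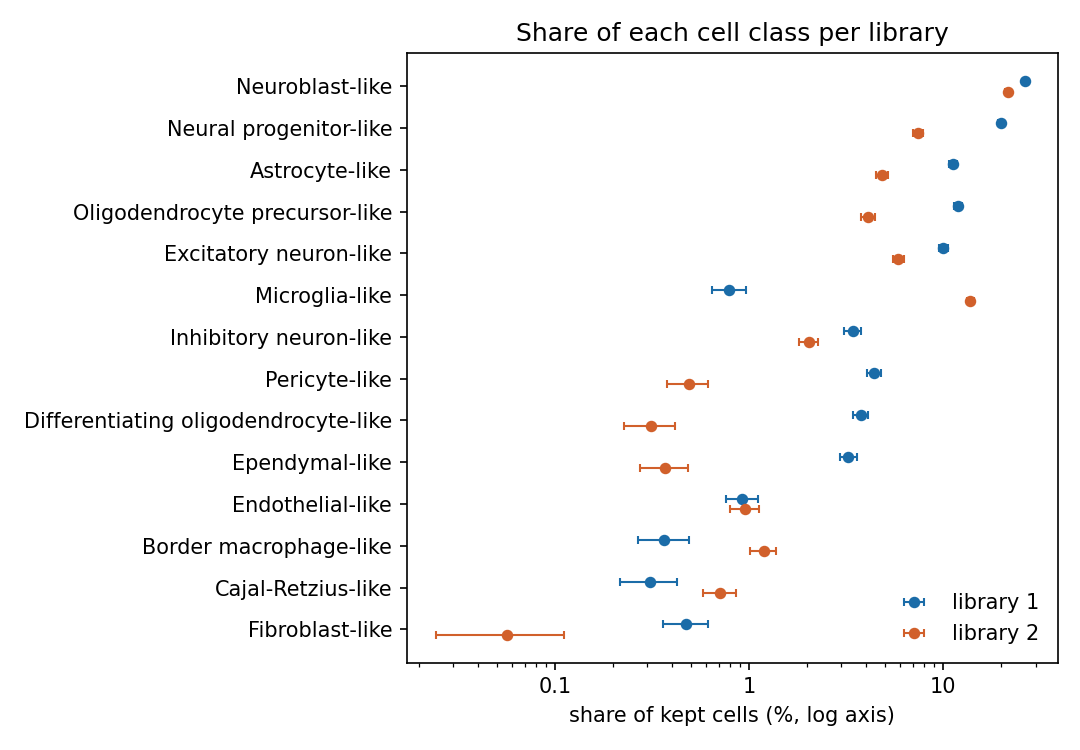
Share of cells per class (%, log axis) in library 1 and library 2, with exact 95% Clopper-Pearson intervals. Microglia-like cells lie at 0.792% and 13.9%, endothelial-like cells at 0.926% and 0.949%.

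After thinning to 2000 UMIs, 81.1% ± 2.09 of neural progenitor-like cells had UMIs of at least 3 genes of the G2 and M phases of division (SD, n = 2), and the list took 14381 ± 329 CPM. This partly restates how the class was drawn. A cluster of 1316 and 565 of its cells, led by histone genes, Pbk and Top2a with no progenitor marker among its 10 leading genes, had 99.9% ± 0.109. Without it the share was 56.3% ± 5.15 at 8132 ± 363 CPM. The rest was unlike, with 43.9% ± 6.50 at 3588 ± 286 CPM in a cluster led by Helt and 86.7% ± 1.59 at 15362 ± 1925 CPM in one led by Tesc. In excitatory and inhibitory neuron-like cells, named after neurons that no longer divide, the shares were 9.55% ± 0.274 and 9.35% ± 1.44. The list took 720.2 ± 11.0 and 704 ± 86.4 CPM there, and these values were taken as the background of this measure. The name of most excitatory neuron-like cells is uncertain, though. Differentiating oligodendrocyte-like cells had 6.53% (4.42 to 9.25) at 650 CPM in library 1 and 11.4% (3.79 to 24.6) at 789 CPM in library 2. Excitatory neuron-like cells had a median of 3422 and 3315 UMIs in libraries 1 and 2, inhibitory neuron-like cells 2168 and 2181. Ependymal-like cells reached 56.9% ± 1.24 at 4855 ± 191 CPM, but 35.1% without Tubb4b, a tubulin gene of the list that cilia also use. Oligodendrocyte precursor-like cells stood at 28.2% ± 5.69 and 4523 ± 1621 CPM, astrocyte-like cells at 31.4% ± 7.59 and 4438 ± 2096 CPM, and microglia-like cells at 34.8% ± 7.92 and 3554 ± 657 CPM. Neuroblast-like cells had 32.0% ± 4.46 at 1795 ± 229 CPM, after 1926 cells of library 1 and 1847 of library 2 were left out as too shallow. Endothelial-like cells had 18.6% ± 1.01 at 1674 ± 501 CPM. Pericyte-like cells had 22.97% (19.4 to 26.9) in library 1 and 12.5% (5.55 to 23.2) in library 2, and the latter interval held the background. Without thinning the shares were 86.6% in progenitor-like, 83.0% in ependymal-like, 55.6% in astrocyte-like, 53.5% in endothelial-like, 46.5% in microglia-like, 42.02% in oligodendrocyte precursor-like, 32.4% in pericyte-like, 22.5% in excitatory neuron-like, 22.1% in neuroblast-like and 12.3% in inhibitory neuron-like cells. Classes whose order by share and by CPM disagreed, such as microglia-like and oligodendrocyte precursor-like cells, are given without an order, and free RNA, which was not removed, adds to each share.

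**Figure D2:**
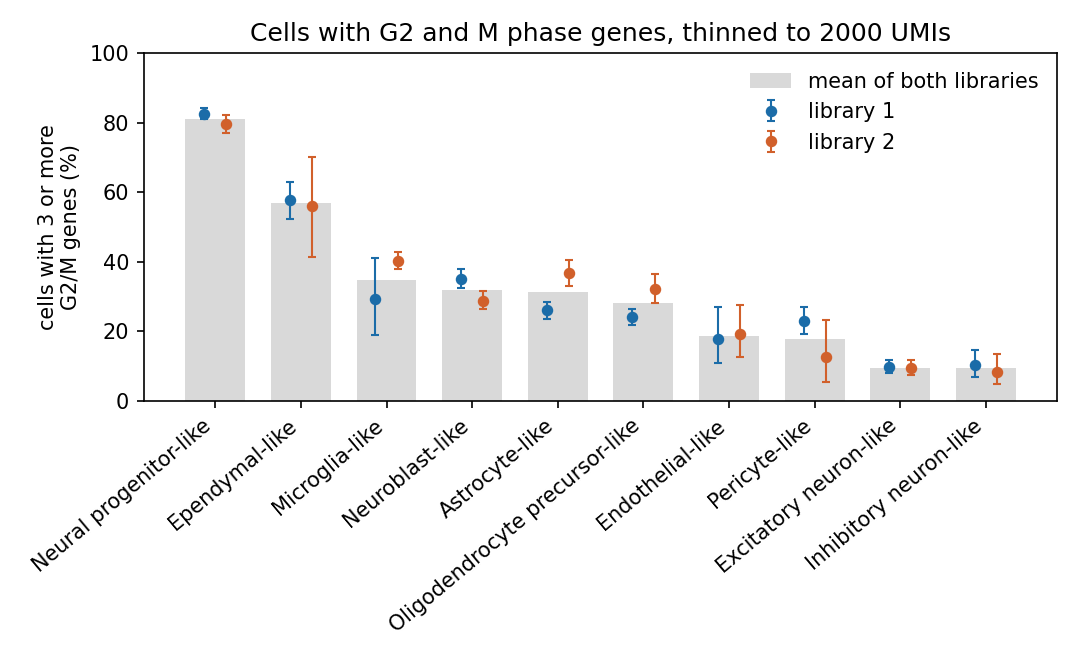
Share of cells with at least 3 G2 and M phase genes after thinning to 2000 UMIs (%, linear axis from 0); bars are means, points are libraries with exact 95% intervals. Neural progenitor-like cells lie at 81.1%, excitatory and inhibitory neuron-like cells at 9.55% and 9.35%.

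Microglia-like cells were compared with the mean of the other classes. Psmb8, a subunit of the immunoproteasome, was at 233 ± 48.0 CPM against 7.75 ± 1.80 CPM (SD, n = 2), 30.02-fold higher (adjusted p = 8.1e-25, edgeR quasi-likelihood F test, Benjamini-Hochberg). Tyrobp, the signalling adaptor of many myeloid receptors (ENSMUSG00000030579, mm10 chromosome 7, 30413760 to 30417585), was at 3597 ± 794 CPM against 9.005 ± 11.6 CPM (adjusted p = 4.3e-26). These were 3035 against 0.828 CPM in library 1 and 4159 against 17.2 CPM in library 2. Ctss, a lysosomal protease (ENSMUSG00000038642, mm10 chromosome 3, 95526786 to 95556403), was at 1769 ± 203 CPM against 3.92 ± 5.10 CPM (adjusted p = 1.2e-26), 1625 against 0.312 CPM in library 1 and 1913 against 7.53 CPM in library 2. Lamb1, a laminin chain, had 0 counts against 61.0 ± 10.1 CPM elsewhere, at least 123-fold lower (adjusted p = 5.8e-07). In all, 2527 genes were higher and 1770 lower out of 13347 tested, and for 86 of these 4297 the mean CPM went the other way. Lysosomal genes, such as Ctss, were higher in 30 of 32 cases (camera, adjusted p = 3.5e-19). All 13 MHC class I genes were higher (adjusted p = 4.0e-09), with Psmb9, another subunit of the immunoproteasome, at 80.6 ± 15.8 CPM against 3.76 ± 1.24 CPM. Dissociation and immediate early genes were higher in 26 of 28 cases (adjusted p = 3.6e-16), with the chemokine gene Ccl3 at 1739.7 ± 163 CPM against 3.47 ± 2.01 CPM, 1855 against 2.06 CPM in library 1 and 1624 against 4.89 CPM in library 2. The axon tract programme, a set described in young microglia, had 17 of 18 members higher and 1 lower (adjusted p = 7.2e-12), and Spp1, osteopontin, was at 1152 ± 799 CPM against 4.31 ± 5.88 CPM, 587 against 0.158 CPM in library 1 and 1717 against 8.47 CPM in library 2. With no other macrophage class in the fit, this does not tell such a programme from genes of microglia or macrophages in general. Basement membrane genes, a list also called in simulated counts without a change in it, were lower in 9 of 21 cases and higher in 2 (adjusted p = 3.4e-04), and Wnt genes lower in 9 of 31 and higher in 4 (adjusted p = 2.3e-04). Wnt5a, a secreted Wnt ligand, was 38.2-fold lower by pooled counts (95% interval 13.05 to 186) at 0.261 ± 0.368 CPM against 20.2 ± 0.611 CPM. These 6 lists were also called with an estimated correlation, at adjusted p = 0.00352 to 0.0425, and the lists that follow were not. Interferon response genes were higher in 14 of 21 cases (adjusted p = 2.9e-05, and adjusted p = 0.0597 with an estimated correlation), with Cxcl10 at 379.7 ± 81.8 CPM against 1.90 ± 0.613 CPM and Bst2 at 272 ± 67.6 CPM against 51.2 ± 4.46 CPM. S phase genes were higher in 15 of 30 cases (adjusted p = 0.00180, and adjusted p = 0.457 with an estimated correlation) and G2 and M phase genes in 28 of 42 (adjusted p = 1.6e-04, and adjusted p = 0.467 with an estimated correlation), with Mki67, a protein of dividing cells, at 111 ± 27.5 CPM against 39.4 ± 2.30 CPM. Lower were 6 of 22 cholesterol biosynthesis genes, with 1 higher (adjusted p = 0.0266, and adjusted p = 0.268 with an estimated correlation), 7 of 18 glutamate receptor genes (adjusted p = 5.6e-04, and adjusted p = 0.170 with an estimated correlation) and 4 of 13 GABA receptor genes (adjusted p = 2.2e-04, and adjusted p = 0.140 with an estimated correlation). Sodium and potassium channels were lower in 5 of 27 cases and higher in 4 (adjusted p = 0.0227, and adjusted p = 0.104 with an estimated correlation). Sqle, a cholesterol enzyme, was at 7.58 ± 1.80 CPM against 49.1 ± 1.74 CPM and Scn3a, a sodium channel gene, at 0.261 ± 0.368 CPM against 27.2 ± 1.71 CPM. Adjusted over the list alone, all these counts were the same. With DESeq2's test 2146 genes were higher and 2546 lower, 45.7% of calls higher, the median log2 fold change of all genes moved from 0.03 to -0.11 (to -0.135 with its size factors), and at a log2 threshold of 2 Sqle was not called. With that test Fcgr1, Lrrc25, Tnf, Vav1, Pik3ap1 and Tifab, also named by the rule, lost their call (adjusted p = 0.0568 to 0.122, DESeq2). The channel list was not called with doublets kept (adjusted p = 0.118).

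Astrocyte-like cells were compared with the other classes of the first fit, which held no differentiating oligodendrocyte-like cells. They stood apart by Tnc, the matrix protein tenascin C (ENSMUSG00000028364, mm10 chromosome 4, 63959785 to 64047015), at 409 ± 49.2 CPM against 3.62 ± 0.7004 CPM (SD, n = 2), 113-fold higher (adjusted p = 3.2e-30, edgeR quasi-likelihood F test). Hmgcs1, an early enzyme of cholesterol synthesis (ENSMUSG00000093930, mm10 chromosome 13, 119690379 to 119708260), was at 738 ± 34.2 CPM against 89.7 ± 1.62 CPM, 8.23-fold higher (adjusted p = 1.4e-25). Dio2, the enzyme that activates thyroid hormone, was 32.8-fold higher at 34.7 ± 0.519 CPM against 1.06 ± 0.132 CPM. Scrt1, a transcription factor of neurons, was 34.7-fold lower at 0.778 ± 0.0108 CPM against 27.0 ± 0.132 CPM (adjusted p = 1.9e-07). Of 13347 genes tested, 2427 were higher and 391 lower by the fitted values. For 446 of these 2818 genes the mean CPM went the other way, and for 1136 at least 1 other class had no counts. With 4000 variable genes 228 genes were lower, out of 11876 tested. Cholesterol biosynthesis genes were higher in 21 of 22 cases and lower in 1 (camera, adjusted p = 4.9e-13), with Tm7sf2, a sterol reductase, at 55.5 ± 1.76 CPM against 6.18 ± 0.304 CPM. Glial synapse-forming and pruning factors were higher in 19 of 23 cases (adjusted p = 9.7e-11), with Chrdl1, a secreted synapse factor, at 31.8 ± 10.2 CPM against 2.10 ± 0.123 CPM. Wnt genes were higher in 24 of 31 cases (adjusted p = 1.5e-06), with Wnt7b at 34.0 ± 1.40 CPM against 4.32 ± 0.347 CPM and Fzd10, a Wnt receptor, at 6.60 ± 2.15 CPM against 0.481 ± 0.0753 CPM. These 3 lists were also called with an estimated correlation, at adjusted p = 0.00657 to 0.0178, and the lists that follow were not. Notch genes were higher in 11 of 22 cases and lower in 2 (adjusted p = 0.00515, and adjusted p = 0.205 with an estimated correlation), with Lfng, which adds sugars to Notch, at 79.1 ± 7.33 CPM against 8.45 ± 1.90 CPM. Notch3 was called higher by the fit at 34.8 ± 2.19 CPM against 42.6 ± 6.01 CPM, a ratio of 0.818, because the fit averages logarithms over classes and some of these had few or no counts. Of the axon tract programme 9 of 18 genes were higher (adjusted p = 0.00235, and adjusted p = 0.215 with an estimated correlation), with Apoe, a lipid carrier, at 12256 ± 2285 CPM against 2264 ± 424 CPM and Axl, a receptor kinase, at 35.3 ± 0.646 CPM against 19.2 ± 1.23 CPM. Hormone response genes were higher in 10 of 19 cases and lower in 2 (adjusted p = 0.0261, and adjusted p = 0.365 with an estimated correlation), with Rxrg, a retinoid receptor, at 10.5 ± 2.20 CPM against 0.9496 ± 0.363 CPM. G2 and M phase genes were higher in 26 of 42 cases (adjusted p = 0.00283, and adjusted p = 0.608 with an estimated correlation), with Nuf2, a kinetochore protein, at 48.4 ± 11.9 CPM against 31.2 ± 0.377 CPM. Glycolysis genes were higher in 5 of 15 with 1 lower (adjusted p = 0.00729, and adjusted p = 0.595 with an estimated correlation), with Ldhb at 832 ± 122 CPM against 284 ± 2.21 CPM. Each of these counts was the same adjusted over the list alone. With doublets kept, the hormone list was no longer called (adjusted p = 0.124), and at a log2 threshold of 2 Ldhb was not called. In simulated counts with only the Notch list changed, camera called 6 of 19 other lists: oxidative phosphorylation, interferon response, channels, basement membrane, growth factors and cytokines, and the Wnt list, which was called in the real counts too.

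Endothelial-like cells, which line vessels, carried Slc38a5, a glutamine transporter (ENSMUSG00000031170, mm10 chromosome X, 8271133 to 8280179), at 716 ± 30.2 CPM (SD, n = 2). The other classes of the first fit had 0.373 ± 0.311 CPM (adjusted p = 7.1e-32, edgeR quasi-likelihood F test), 737 against 0.593 CPM in library 1 and 695 against 0.153 CPM in library 2. Slc22a8, an organic anion transporter (ENSMUSG00000063796, mm10 chromosome 19, 8591254 to 8611835), was at 351 ± 25.5 CPM against 7.95 ± 0.254 CPM, 44.2-fold higher (adjusted p = 3.9e-28). Fn1, fibronectin, was 29.9-fold higher at 661 ± 45.6 CPM against 22.1 ± 0.627 CPM (adjusted p = 3.8e-30). Ctnnd2, a catenin of neurons, had 0 counts against 69.2 ± 7.59 CPM, at least 31.2-fold lower (adjusted p = 7.0e-11). Of 13347 genes tested, 1924 were higher and 1507 lower, and for 63 of these 3431 the mean CPM went the other way. All 21 blood-brain barrier transporters were higher (camera, adjusted p = 2.9e-21), which partly restates the name of the class. Basement membrane genes were higher in 15 of 21 cases (adjusted p = 8.0e-09), with Lama4, a laminin chain, at 212 ± 9.47 CPM against 45.0 ± 0.620 CPM. MHC class I genes were higher in 11 of 13 cases, 12 adjusted over the list alone (adjusted p = 5.2e-07), with Psmb9 at 22.97 ± 9.64 CPM against 10.2 ± 1.59 CPM and Erap1, a peptide-trimming enzyme, at 22.1 ± 10.2 CPM against 7.16 ± 2.43 CPM. Sodium and potassium channels were lower in 9 of 27 cases and higher in 3 (adjusted p = 8.3e-04). These 4 lists were also called with an estimated correlation, at adjusted p = 0.00436 to 0.0344, and the lists that follow were not. Interferon response genes were higher in 15 of 21 cases (adjusted p = 2.7e-05, and adjusted p = 0.0784 with an estimated correlation), with Bst2, which tethers virus particles, at 239 ± 27.9 CPM against 54.9 ± 0.0552 CPM and Isg15, a ubiquitin-like protein, at 53.3 ± 11.0 CPM against 6.72 ± 2.999 CPM. Wnt genes were higher in 16 of 31 and lower in 4 (adjusted p = 0.0121, and adjusted p = 0.156 with an estimated correlation), with Notum, which inactivates Wnt proteins, at 74.7 ± 8.08 CPM against 1.84 ± 0.139 CPM. Dissociation and immediate early genes were higher in 13 of 28 and lower in 2 (adjusted p = 0.004997, and adjusted p = 0.156 with an estimated correlation), with Klf2, a transcription factor induced by blood flow, at 506 ± 44.0 CPM against 20.5 ± 1.71 CPM and its relative Klf4 at 79.8 ± 11.7 CPM against 10.4 ± 0.212 CPM. Lysosomal genes were higher in 9 of 32 and lower in 1 (adjusted p = 0.0140, and adjusted p = 0.276 with an estimated correlation), with Ctsh, a protease, at 529 ± 75.4 CPM against 64.3 ± 0.962 CPM and Lipa, a lipase, at 124 ± 29.5 CPM against 20.6 ± 4.14 CPM. Glutamate receptor genes were lower in 8 of 18 cases (adjusted p = 3.1e-05, and adjusted p = 0.137 with an estimated correlation), with Gria4 at least 7.66-fold lower at 0 CPM against 17.0 ± 2.75 CPM. GABA receptor genes were lower in 3 of 13 (adjusted p = 5.9e-04, and adjusted p = 0.156 with an estimated correlation). Cholesterol biosynthesis genes were lower in 9 of 22 (adjusted p = 0.00627, and adjusted p = 0.156 with an estimated correlation), with Hmgcs1 at 30.3 ± 1.35 CPM against 168 ± 2.03 CPM. Of the axon tract programme 5 of 18 genes were lower and 1 higher (adjusted p = 0.0362, and adjusted p = 0.276 with an estimated correlation), with Cd63, a protein of endosomes, at 11.8 ± 0.119 CPM against 338 ± 5.88 CPM. Except for the MHC list, counts adjusted over the list alone were the same. The axon tract call was lost with doublets kept (adjusted p = 0.0889) and with all genes past the filter as background (0.0505), and at a log2 threshold of 2 Hmgcs1 was not called. With DESeq2 the median log2 fold change of all genes moved from -0.21 to -0.07. Slco1a4, Myct1, Abcb1a and Gabra2, named by the rule, lost their call with the DESeq2 test (adjusted p = 0.0717 to 0.0897). In simulated counts without a change in them, camera also called the basement membrane list, even with an estimated correlation, the channel list, and growth factors and cytokines.

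Pericyte-like cells, the mural cells of capillaries, were compared with endothelial-like cells. The class was 1 cluster with 6 pericyte and 3 smooth muscle markers (Acta2, Tagln and Myl9) among its 10 leading genes. A smooth muscle-like class of 0.523%, 0.433% and 0.348% of cells appeared with stricter limits, at resolution 2 and with 4000 variable genes. Heyl, a target gene of Notch signalling (ENSMUSG00000032744, mm10 chromosome 4, 123233556 to 123249875), was at 189 ± 56.1 CPM (SD, n = 2) against 0 CPM, at least 85.1-fold higher over a floor of 3 counts (adjusted p = 1.2e-12, edgeR quasi-likelihood F test). Pth1r, a hormone receptor, was at least 78.7-fold higher at 175 ± 12.9 CPM, and Axl, a receptor kinase, at least 65.7-fold higher at 146 ± 9.58 CPM. Podxl, a sialomucin of the vessel lumen (ENSMUSG00000025608, mm10 chromosome 6, 31519488 to 31563981), had 0 counts in pericyte-like cells against 158 ± 6.82 CPM, at least 124-fold lower (adjusted p = 3.3e-13). Mfsd2a, a lipid transporter of the blood-brain barrier (ENSMUSG00000028655, mm10 chromosome 4, 122946850 to 122961188), was at 1.44 ± 2.04 CPM against 740.1 ± 112 CPM, a log2 fold change of -8.29 ± 0.34 (adjusted p = 9.4e-19). It was at 2.88 against 819 CPM in library 1 and 0 against 661 CPM in library 2. Of 13347 genes tested, 1269 were higher and 1120 lower. All 21 blood-brain barrier transporters were lower (camera, adjusted p = 8.2e-23), which partly restates the name of the endothelial-like class. Their levels in single libraries were 0 to 85.6 CPM in pericyte-like and 14.9 to 1506 CPM in endothelial-like cells. All 21 were lower in both libraries. This list was also called with an estimated correlation (adjusted p = 0.00677), and the lists that follow were not. Oxidative phosphorylation genes were higher in 3 of 47 cases and lower in 1 (adjusted p = 0.00256, and adjusted p = 0.985 with an estimated correlation), with Ndufs7 at 551 ± 20.05 CPM against 202 ± 15.7 CPM and Cox8a, both parts of respiratory complexes, at 3504 ± 588 CPM against 1384 ± 2.47 CPM. S phase genes were higher in 7 of 30 cases, 8 adjusted over the list alone (adjusted p = 0.0268, and adjusted p = 0.985 with an estimated correlation), with Mcm4, a replication helicase subunit, at 27.7 ± 9.77 CPM against 5.88 ± 6.22 CPM, 34.6 against 1.49 CPM in library 1 and 20.8 against 10.3 CPM in library 2. The other counts were the same adjusted over the list alone. At a log2 threshold of 2, Ndufs7 and Cox8a were not called. Il34, Fam162b, Anpep, Myct1, Scgb3a1, Sox7 and Samsn1, also named by the rule, lost their call with the DESeq2 test (adjusted p = 0.391 to 0.507), as did E2f8 (adjusted p = 0.0555). Library 2 held 69 pericyte-like cells.

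**Figure D3:**
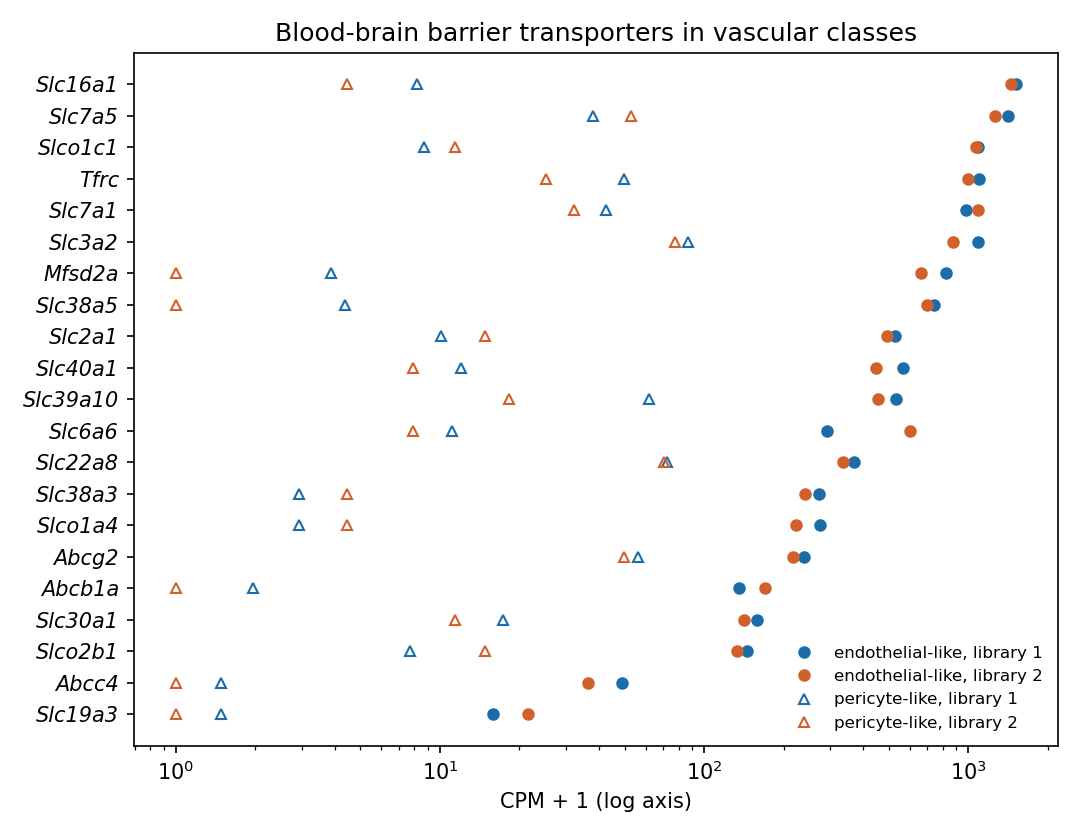
CPM + 1 (log axis) of 21 blood-brain barrier transporters in endothelial-like (filled circles) and pericyte-like cells (open triangles) of each library. Levels in single libraries span 14.9 to 1506 CPM in endothelial-like and 0 to 85.6 CPM in pericyte-like cells. All 21 were lower in pericyte-like cells in both libraries.

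Excitatory neuron-like cells were compared with inhibitory neuron-like cells. Of the former 970 of 1202 in library 1 and 650 of 832 in library 2 formed a cluster led by Neurod1, Gal, Tac2, Calb2 and Prox1, with 0 excitatory neuron markers among its 10 leading genes. The name of most of these cells is thus uncertain. Emx1, a transcription factor of the dorsal forebrain (ENSMUSG00000033726, mm10 chromosome 6, 85187438 to 85204462), was at 198 ± 14.9 CPM against 1.31 ± 1.85 CPM (SD, n = 2; adjusted p = 5.0e-12, edgeR quasi-likelihood F test), 173-fold higher by pooled counts (95% interval 47.9 to 1433). Adra2c, an adrenergic receptor gene, was at 43.3 ± 0.945 CPM against 0 CPM, at least 24.9-fold higher (adjusted p = 6.3e-08). Sox1, a transcription factor of neural precursors and some inhibitory neurons (ENSMUSG00000096014, mm10 chromosome 8, 12395295 to 12400126), was at 4.68 ± 1.27 CPM against 114 ± 8.35 CPM, a log2 fold change of -4.66 ± 0.26 (adjusted p = 8.0e-15). Slit1, an axon guidance protein, was 43.7-fold lower at 0.878 ± 0.238 CPM against 38.4 ± 2.98 CPM, and Asap1 18.3-fold lower at 5.85 ± 1.58 CPM against 107 ± 0.255 CPM. Dlx1as, a transcript antisense to Dlx1, was at 1.17 ± 0.317 CPM against 62.8 ± 16.8 CPM. Calls over 13347 genes tested numbered 497 higher and 300 lower. Every list called here lost its call with an estimated correlation. Wnt genes were higher in 6 of 31 cases, 9 adjusted over the list alone, and lower in 2 (adjusted p = 3.1e-04, and adjusted p = 0.112 with an estimated correlation). The transcription factor gene Lef1 was at least 9.13-fold higher at 15.8 ± 1.69 CPM against 0 CPM. GABA receptor genes were lower in 3 of 13 cases, 4 adjusted over the list alone, and higher in 1 or, over the list alone, 2 (adjusted p = 0.0186, and adjusted p = 0.716 with an estimated correlation), with Gabrg3 at 0.766 ± 0.590 CPM against 11.7 ± 1.91 CPM, 1.18 against 10.4 CPM in library 1 and 0.349 against 13.1 CPM in library 2. MHC class I genes were called higher as a list with 0 of 13 members called by either count (adjusted p = 0.00760, and adjusted p = 0.112 with an estimated correlation). Cholesterol biosynthesis genes were lower in 1 of 22 members by either count (adjusted p = 0.0328, and adjusted p = 0.690 with an estimated correlation), and that list was not called with DESeq2 size factors (adjusted p = 0.0541) or with all genes past the filter as background (0.0678). The member was Idi1 at 13.8 ± 4.14 CPM against 29.3 ± 2.59 CPM, not called without the low-count filter or at a log2 threshold of 2. Without the cluster led by Neurod1, 140 of the 497 higher and 105 of the 300 lower genes were called again, among 216 and 152 in all. With as few cells drawn once at random from the whole class these were 336 and 175, among 354 and 216, so fewer cells account for part of the loss. Of 20 genes named by the rule and tested without the cluster, 7 lost the call at the same sign, and Lef1 lost it as well. In the drawn cells 0 lost it. Without the cluster some of the 7 still had large log2 fold changes, though not called. Cldn3 was at 4.10 ± 1.27 (adjusted p = 0.0766) and Dusp14 at 3.47 ± 1.46 (adjusted p = 0.265), while Idi1 was at -0.33 ± 0.34 (adjusted p = 0.757). Lef1 had a log2 fold change of -0.0014 (adjusted p = 1). With looser and stricter quality limits 374 and 365 genes were higher and 449 and 401 lower, 235 and 181 of the higher and 169 and 116 of the lower ones shared. Wnt7b, called higher at 7.78 ± 2.31 CPM against 0 CPM, was not called with looser or stricter limits or with 4000 variable genes (adjusted p = 0.689, 0.762 and 0.364). At Leiden resolution 0.5 428 genes were higher and 427 lower, 254 and 145 of them shared, and 12 were called in the opposite direction. Among these Wnt7b was called lower, with a log2 fold change of -3.55 (adjusted p = 5.6e-07).

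Oligodendrocyte precursor-like cells were compared with astrocyte-like cells, the other main glial class. Npas1, a transcription factor (ENSMUSG00000001988, mm10 chromosome 7, 16455721 to 16477728), was at 46.04 ± 5.66 CPM against 0.362 ± 0.142 CPM (SD, n = 2). Its log2 fold change was 6.80 ± 0.54 (standard error, adjusted p = 7.6e-12, edgeR quasi-likelihood F test). Gsx1, a homeobox factor, was 57.4-fold higher at 37.1 ± 0.917 CPM against 0.647 ± 0.174 CPM. Tnc was lower by a log2 fold change of -8.05 ± 0.26, at 1.60 ± 0.462 CPM against 409 ± 49.2 CPM (adjusted p = 4.2e-21). Apoe (ENSMUSG00000002985, mm10 chromosome 7, 19696109 to 19699188) was 33.2-fold lower at 369 ± 67.1 CPM against 12256 ± 2285 CPM (adjusted p = 1.7e-17). Of 13347 genes tested, 1077 were higher and 1723 lower. Wnt genes were lower in 17 of 31 cases and higher in 1 (camera, adjusted p = 4.4e-06), with Notum 90.3-fold lower by pooled counts (95% interval 15.9 to 3601) at 0.0797 ± 0.113 CPM against 10.2 ± 0.0318 CPM. Basement membrane genes were lower in 12 of 21 and higher in 1 (adjusted p = 1.8e-05), with Lama5, a laminin chain, at 0 CPM against 6.65 ± 2.36 CPM, at least 19.6-fold lower. Glial synapse-forming and pruning factors were lower in 13 of 23 and higher in 2 (adjusted p = 1.8e-05), with Tnc among them. Of the axon tract programme 9 of 18 genes were lower, 10 adjusted over the list alone (adjusted p = 1.1e-06), with Apoe among them. These 4 lists were also called with an estimated correlation, at adjusted p = 0.0303 to 0.0362, and the lists that follow were not. Glutamate receptor genes were higher in 10 of 18 cases, 11 adjusted over the list alone, and lower in 3 (adjusted p = 0.0171, and adjusted p = 0.315 with an estimated correlation), with Gria3 at 90.2 ± 13.6 CPM against 9.44 ± 0.718 CPM and Grik3 at 28.1 ± 2.64 CPM against 0.701 ± 0.120 CPM. Sodium and potassium channels were higher in 10 of 27 and lower in 4 (adjusted p = 0.0484, and adjusted p = 0.179 with an estimated correlation), with Scn3a at 62.5 ± 3.21 CPM against 1.86 ± 0.414 CPM. Dissociation and immediate early genes were lower in 13 of 28 (adjusted p = 1.8e-04, and adjusted p = 0.0990 with an estimated correlation), with Socs3, an inhibitor of cytokine signalling, at 5.36 ± 0.597 CPM against 39.7 ± 13.2 CPM. Lysosomal genes were lower in 9 of 32 (adjusted p = 2.6e-04, and adjusted p = 0.175 with an estimated correlation), with the proteases Ctsc at 1.25 ± 0.415 CPM against 35.0 ± 9.80 CPM and Ctsh at 0.625 ± 0.207 CPM against 9.46 ± 0.785 CPM. Notch genes were lower in 10 of 22 and higher in 4 (adjusted p = 0.0272, and adjusted p = 0.201 with an estimated correlation), with Lfng at 2.03 ± 0.397 CPM against 79.1 ± 7.33 CPM. Interferon response genes were lower in 7 of 21 and higher in 1 (adjusted p = 0.00815, and adjusted p = 0.201 with an estimated correlation), with Ifitm3, an antiviral membrane protein, at 1.49 ± 0.0765 CPM against 123 ± 36.0 CPM. Growth factors and cytokines were lower in 13 of 34 and higher in 5 or, adjusted over the list alone, 6 (adjusted p = 0.0272, and adjusted p = 0.315 with an estimated correlation), with Bdnf, a neurotrophin, at 0 CPM against 4.33 ± 0.197 CPM, at least 12.8-fold lower. Cholesterol biosynthesis genes were lower in 2 of 22 (adjusted p = 0.00631, and adjusted p = 0.179 with an estimated correlation), with Hmgcs1 at 264 ± 6.89 CPM against 738 ± 34.2 CPM. Counts adjusted over the list alone were otherwise the same. With doublets kept the glutamate receptor, channel and Notch lists were not called (adjusted p = 0.0501, 0.0964 and 0.165), nor was the channel list with DESeq2 size factors (0.0637), without the low-count filter (0.0722) or without the progenitor-like cluster led by histone genes (0.0727). At a log2 threshold of 2, Hmgcs1 was not called.

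Border macrophage-like cells were compared with microglia-like cells, in a fit added after seeing the data. Tslp, a cytokine (ENSMUSG00000024379, mm10 chromosome 18, 32815383 to 32819797), was at 131 ± 3.38 CPM against 0.170 ± 0.241 CPM (SD, n = 2; adjusted p = 1.1e-14, edgeR quasi-likelihood F test), 412-fold higher by pooled counts (95% interval 111 to 3441). Cd38, an enzyme that breaks down NAD (ENSMUSG00000029084, mm10 chromosome 5, 43868553 to 43912375), was 272-fold higher by pooled counts (95% interval 90.6 to 1339) at 131 ± 2.28 CPM against 0.255 ± 0.361 CPM (adjusted p = 2.7e-13). Slc2a5, a fructose transporter (ENSMUSG00000028976, mm10 chromosome 4, 150119283 to 150144169), had 0 counts against 43.0 ± 17.7 CPM, at least 11.8-fold lower (adjusted p = 2.0e-06). Slc16a3, a lactate transporter, was at least 6.88-fold lower at 0 CPM against 25.2 ± 3.30 CPM, and Csf1, a macrophage growth factor, 28.3-fold lower by pooled counts (95% interval 7.78 to 234) at 11.2 against 67.2 CPM in library 1 and 0 against 69.0 CPM in library 2. Of 13331 genes tested, 328 were higher and 477 lower. Interferon response genes were higher in 12 of 23 cases, 13 adjusted over the list alone, and lower in 1 (camera, adjusted p = 1.5e-10, and adjusted p = 0.0451 with an estimated correlation), with Rsad2, an antiviral enzyme, at 44.7 ± 8.19 CPM against 1.28 ± 1.81 CPM, 50.5 against 0 CPM in library 1 and 38.9 against 2.55 CPM in library 2. The call of this list held with an estimated correlation, and those of the lists that follow did not. Of the axon tract programme 9 of 18 genes were lower, 10 adjusted over the list alone, and 4 higher (adjusted p = 0.00316, and adjusted p = 0.396 with an estimated correlation), with Csf1 among the lower. Glycolysis genes were lower in 5 of 15 cases by either count (adjusted p = 0.00208, and adjusted p = 0.869 with an estimated correlation), with Ldhb, a lactate dehydrogenase chain, at 44.4 ± 23.1 CPM against 435 ± 54.1 CPM, 28.0 against 397 CPM in library 1 and 60.7 against 473 CPM in library 2. The split of calls moved with the scaling, to 459 higher and 273 lower with DESeq2 size factors (62.7% higher), while the median of all genes moved from -0.24 to -0.03. DESeq2, which also changes the test, called 426 and 169 (71.6% higher), and a fit of both classes alone, on 5387 genes, called 307 and 249. Lbx1, Ifi208, Timd4, Ifi211 and Itgax, named by the rule, lost their call with the DESeq2 test (adjusted p = 0.7455 to 0.927). Library 1 held 44 border macrophage-like cells.

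Differentiating oligodendrocyte-like cells were compared with oligodendrocyte precursor-like cells, also in the added fit. Epcam, an adhesion protein (ENSMUSG00000045394, mm10 chromosome 17, 87635979 to 87651129), was at 155 ± 44.5 CPM against 0.273 ± 0.156 CPM (SD, n = 2; adjusted p = 6.7e-20, edgeR quasi-likelihood F test), 795-fold higher by pooled counts (95% interval 219 to 6582). Lpar1, a receptor for lysophosphatidic acid, was 274-fold higher by pooled counts (95% interval 74.9 to 2280.2) at 55.1 ± 12.8 CPM against 0.162 ± 0.230 CPM. Cdk1, the kinase that drives mitosis (ENSMUSG00000019942, mm10 chromosome 10, 69335146 to 69352938), was at 2.81 ± 1.04 CPM against 112 ± 34.7 CPM, a log2 fold change of -5.54 ± 0.59 (adjusted p = 3.8e-10). Ube2c, a ubiquitin-conjugating enzyme of mitosis, was 49.4-fold lower at 7.51 ± 0.599 CPM against 371 ± 132 CPM. A cluster of 112 and 80 of the precursor-like cells had Ube2c, Aspm and Nusap1 among its 10 leading genes. How far the lower division genes rest on that cluster was not tested. Of 13331 genes tested, 651 were higher and 1251 lower. Every list called here lost its call with an estimated correlation. G2 and M phase genes were lower in 38 of 42 cases, 39 adjusted over the list alone (adjusted p = 1.3e-21, and adjusted p = 0.208 with an estimated correlation). S phase genes were lower in 18 of 30, 21 adjusted over the list alone (adjusted p = 2.0e-10, and adjusted p = 0.208 with an estimated correlation), with Ung, a DNA repair enzyme, 42.5-fold lower by pooled counts (95% interval 7.47 to 1691) at 0.172 ± 0.244 CPM against 11.9 ± 4.94 CPM. Glycolysis genes were higher in 7 of 15 and lower in 1 by either count (adjusted p = 1.0e-04, and adjusted p = 0.288 with an estimated correlation), with Tpi1 at 426 ± 76.4 CPM against 139 ± 7.97 CPM and Hk2 at 17.8 ± 5.10 CPM against 3.62 ± 0.301 CPM. Oxidative phosphorylation genes were called higher as a list with 0 of 47 members called by either count (adjusted p = 1.0e-04, and adjusted p = 0.510 with an estimated correlation). Sodium and potassium channels were lower in 15 of 27 and higher in 1 by either count (adjusted p = 6.2e-04, and adjusted p = 0.208 with an estimated correlation), with Kcnj16 15.2-fold lower by pooled counts (95% interval 2.59 to 616) at 0.172 ± 0.244 CPM against 4.84 ± 0.197 CPM. Dissociation and immediate early genes were lower in 9 of 28, 10 adjusted over the list alone, and higher in 2 (adjusted p = 0.0230, and adjusted p = 0.208 with an estimated correlation), with Egr1, an activity-induced transcription factor, at 9.23 ± 3.04 CPM against 120.4 ± 4.84 CPM. GABA receptor genes were lower in 5 of 13 (adjusted p = 0.0272, and adjusted p = 0.299 with an estimated correlation) and Notch genes in 10 of 22 (adjusted p = 0.0274, and adjusted p = 0.299 with an estimated correlation) by either count, with Nrarp, a Notch target, at 3.84 ± 0.421 CPM against 37.0 ± 3.48 CPM. Glial synapse-forming and pruning factors were lower in 5 of 22 and higher in 1 by either count (adjusted p = 0.0338, and adjusted p = 0.208 with an estimated correlation), with Gpc5, a glypican, at 2.63 ± 1.29 CPM against 20.2 ± 1.76 CPM, 1.72 against 19.0 CPM in library 1 and 3.54 against 21.5 CPM in library 2. Wnt genes were lower in 5 of 30, 7 adjusted over the list alone, and higher in 2 (adjusted p = 0.0342, and adjusted p = 0.333 with an estimated correlation), with Fzd9, a Wnt receptor, 11.2-fold lower by pooled counts (95% interval 2.98 to 94.9) at 0.345 ± 0.488 CPM against 6.80 ± 0.941 CPM. With doublets kept the dissociation, GABA receptor, synapse, Notch and Wnt lists were not called (adjusted p = 0.0716, 0.102, 0.679, 0.1001 and 0.193), and at a log2 threshold of 2 Tpi1 was not called. Library 2 held 44 differentiating oligodendrocyte-like cells.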

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

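All tests of explanations here were chosen after the results were seen, and no group of the design gives a biological explanation to test.

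The microglia-like share was 0.792% in library 1 and 13.9% in library 2, a signal that no comparison of the design addresses. Shallow barcodes counted as cells are argued against, since among kept cells with at least 1000 genes the ratio of shares was 29.7 in place of 17.5. It was 14.4 to 28.4 with other quality limits for genes and mitochondrial UMIs and with doublets kept. A preparation that kept more of all brain macrophages stays open: the border macrophage-like share was 3.24 times as high in library 2, and the odds ratio of microglia-like to border macrophage-like cells, 5.39 (3.55 to 8.07), compares single libraries with an interval for counting error only. A difference between the mice, the dissection or a preparation step that acts on microglia alone stays open, because the sources used here tie no mouse and no preparation to a library.

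In library 2, 4876 of the kept barcodes (34.5%) fell into low-depth clusters left out of every class, against 22 (0.184%) in library 1. A candidate explanation is barcodes that hold RNA of several cell types, since 3291 of the 4039 such barcodes with at least 800 UMIs (81.5%, 95% interval 80.2 to 82.7) had marker UMIs of at least 3 of 8 lineages after thinning. This was 7.90% of named cells but 46.2% of ependymal-like, 40.6% of pericyte-like and 4 of 8 fibroblast-like cells. Red blood cells are argued against, with a globin share of 4.0% in the median cell of the globin-led cluster in library 2, and so is a lower depth of the whole of library 2, with a ratio of median UMIs of 0.990 over the classes (0.727 to 1.49). Whether the barcodes of the low-depth clusters are broken cells, clumps or droplets with free RNA was not tested.

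Ttr, the transthyretin gene that choroid plexus expresses at high level, led a cluster named astrocyte-like, with 7893 CPM in library 1 and 1029.8 CPM in library 2. A candidate explanation is a few choroid plexus cells inside the cluster, since in library 1, where 26 of its cells held Ttr, 99.9% of its Ttr UMIs came from the 10 richest; in library 2 only 4 cells held Ttr. In all, 10 cells held at least 100 Ttr UMIs, and 9 of these 10 but 0 of 2028 other cells had UMIs of at least 3 of 7 other choroid plexus markers. Free Ttr RNA is argued against only as the source of the cluster's high level, which was 7.70 and 3.63 CPM in libraries 1 and 2 without such cells. Free Ttr RNA at a low level stays open, since Ttr-rich cells do not forbid it. Ttr was found in 3.40% of neural progenitor-like and 5.26% of microglia-like cells of library 1, and in 0.190% and 0.204% in library 2. The comparison of astrocyte-like cells with the other classes without this cluster called 2144 genes higher and 507 lower.

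Globin UMIs, which no comparison uses, made up 0.0274% of UMIs in library 1 and 3.52% in library 2. An unnamed cluster led by Foxp2 held 337 cells, 1.74% of library 1 and 0.906% of library 2. Another, led by Myo1c, held 65 cells, all from library 1. One led by S100a8, a neutrophil gene, held 110 cells, 0.0834% of library 1 and 0.708% of library 2. Barcodes with UMIs of Y-linked genes and none of Xist numbered 2742 in library 1 and 2417 in library 2.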

How the results depend on the processing

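The settings named in what follows were planned, except the fit on both classes alone, the fits without certain clusters or with fewer cells, the list without Tubb4b and lists against all genes past the filter, which were chosen after seeing the data. Of 348 alternative gene counts 316 stayed within 1.5 times and of 63 counts of lists called 51. The 316 include 18 counts for each library left out, which cover only genes already called. Of 90 shares under other settings, counting unnamed cells beside the classes, 12 moved by more than 1.5 times. These lay in 8 groups, of which the unnamed cells were 1. Leaving out 1 of 2 libraries moves a mean by a fixed part of its SD and tests nothing. Of 4970 alternatives for single genes 97 lost the call at the same sign, 31 of them with the DESeq2 test, and 5 turned. The same result was counted for 4489, among them 69 without library 1 and 82 without library 2, for which no call was made. The other 379 moved by more than the spread on leaving out a library. They set a log2 ratio of CPM in 1 library against the fitted value, which are unlike measures, so they do not measure dependence on a library. Of 504 for single lists 429 kept their call and 75 lost it, 53 of them with an estimated correlation and 12 with doublets kept. Except where said, the cause was not tested.

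With stricter quality limits microglia-like cells took 12.3%, unnamed cells 4.96% in place of 19.3%, border macrophage-like cells 1.40%, Cajal-Retzius cell-like cells 1.05%, endothelial-like cells 1.38% and inhibitory neuron-like cells 1.57%. With looser limits endothelial-like cells took 0.912% and inhibitory neuron-like cells 0.767%, with doublets kept endothelial-like cells 1.02% and neuroblast-like cells 18.5%, and with 4000 variable genes endothelial-like cells 0.826% and inhibitory neuron-like cells 1.62%. At Leiden resolution 2 differentiating oligodendrocyte-like cells took 1.10%.

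Shares of cells with cell cycle genes move by construction with depth and the number of genes asked for. Thinned to 1000 UMIs they were 19.98% in astrocyte-like, 10.4% in endothelial-like, 32.2% in ependymal-like, 2.62% in excitatory neuron-like, 3.43% in inhibitory neuron-like, 25.2% in microglia-like, 72.7% in neural progenitor-like, 9.61% in neuroblast-like and 19.1% in oligodendrocyte precursor-like cells. In the same order and then in pericyte-like cells, at least 2 genes gave 54.2%, 37.9%, 80.5%, 28.1%, 28.7%, 50.8%, 87.8%, 54.9%, 45.9% and 37.9%. No thinning gave 55.6%, 53.5%, 83.0%, 22.5%, 12.3%, 46.5%, 86.6%, 22.1%, 42.02% and 32.4%. Without the cluster led by histone genes the share was 56.3% in neural progenitor-like cells. Without Tubb4b the share was 16.4% in endothelial-like, 35.1% in ependymal-like, 6.44% in excitatory neuron-like and 7.13% in inhibitory neuron-like cells. The lowest correlation between libraries was Pearson r 0.8405 with log2(CPM + 10), and 0.543 (Spearman rho 0.616) for genes of at least 10 CPM.

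A log2 threshold of 2 leaves fewer genes by construction. Higher and lower genes were then 1371 and 1102 in microglia-like, 1215 and 104 in astrocyte-like, 1179 and 878 in endothelial-like, 825 and 680 in pericyte-like, 277 and 171 in excitatory neuron-like, 536 and 920.0 in oligodendrocyte precursor-like, 143 and 884 in neuroblast-like, 181 and 215 in border macrophage-like and 257 and 662 in differentiating oligodendrocyte-like cells. With 4000 variable genes 228 genes were lower in astrocyte-like, 317 higher in excitatory neuron-like, 479 higher in neuroblast-like and 297 lower in border macrophage-like cells. Without clusters led by markers of another class 217 were higher and 152 lower in excitatory neuron-like cells, without the cluster led by Neurod1 alone 216 and 152, and with all genes tested 521 were lower there. In neuroblast-like cells 1243 were lower with stricter limits and 1429 higher at Leiden resolution 2. In border macrophage-like cells 273 were lower with DESeq2 size factors, 169 with DESeq2 and 249 in the fit on both classes alone. Without the library block microglia-like cells had 2504 higher and 1803 lower genes and border macrophage-like cells 322 and 438, and Egr2 in differentiating oligodendrocyte-like cells lost its call (adjusted p = 0.0565).

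Lists called with an estimated correlation were 6 of 13 in microglia-like, 3 of 8 in astrocyte-like, 4 of 12 in endothelial-like, 1 of 3 in pericyte-like, 0 of 4 in excitatory neuron-like, 4 of 12 in oligodendrocyte precursor-like, 0 of 7 in neuroblast-like, 1 of 3 in border macrophage-like and 0 of 10 in differentiating oligodendrocyte-like cells. In pericyte-like cells 7 were called without the low-count filter and 9 with doublets kept, and in differentiating oligodendrocyte-like cells 5 with doublets kept. In simulated counts the camera test called 1, 6 and 3 of 19 unchanged lists in the microglia-like, astrocyte-like and endothelial-like comparisons. With an estimated correlation these were 0, 1 and 1 (basement membrane both times). In the comparisons between classes 0 were called, but the simulated genes were independent, so lists of correlated genes are not covered.

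The 5 turned values were log2 fold changes of -0.0018 for Lef1 in excitatory neuron-like cells without clusters led by markers of another class and -0.0014 without the cluster led by Neurod1 alone, -3.55 for Wnt7b there at Leiden resolution 0.5, and 0.060 for Nusap1 and 0.19 for Fam83d in neuroblast-like cells with stricter limits. With 1 library left out no test could be made. Genes already called were instead counted where the other library alone passed the fold threshold. No such count moved beyond 1.5 times, but it can only be part of the main count, so this tests little. At Leiden resolution 0.5 and 2 and with 4000 variable genes, differentiating oligodendrocyte-like cells were under 40 in library 2 and were not tested. In simulated counts, 0% of genes changed 2-fold and 29.9% of those changed 4-fold were recovered in the border macrophage-like comparison, and 3.0% and 31.3% in the pericyte-like comparison.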

Other observations

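The comparison of neuroblast-like with neural progenitor-like cells and the test of pooled sexes were chosen after the data were seen.

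Scn3a, a sodium channel gene of young neurons (ENSMUSG00000057182, mm10 chromosome 2, 65457118 to 65567627), was at 50.4 ± 3.86 CPM against 3.64 ± 1.08 CPM in neuroblast-like and neural progenitor-like cells (SD, n = 2), 13.9-fold higher (adjusted p = 1.8e-14, edgeR quasi-likelihood F test). Grik3, a glutamate receptor gene, was 9.25-fold higher at 30.2 ± 2.04 CPM against 3.26 ± 0.203 CPM, and Actl6b, a chromatin remodelling subunit of neurons, 6.29-fold higher at 83.0 ± 0.848 CPM against 13.2 ± 4.55 CPM. Spc25, a kinetochore protein (ENSMUSG00000005233, mm10 chromosome 2, 69193895 to 69206194), was 33.9-fold lower at 6.36 ± 1.10 CPM against 216 ± 1.13 CPM (adjusted p = 5.4e-14). Zcchc24 was 53.9-fold lower at 1.33 ± 0.262 CPM against 71.9 ± 2.29 CPM. The test called 757 of 13347 genes higher and 1929 lower. The higher ones were 1429 at Leiden resolution 2 (707 shared) and 479 with 4000 variable genes (264 shared), and with stricter quality limits 650 were higher and 1243 lower (369 and 948 shared). Of the progenitor-like cells 1316 of 2386 and 565 of 1050 formed a cluster led by histone genes, Pbk and Top2a with no progenitor marker among its 10 leading genes. Lower division genes in neuroblast-like cells thus partly restate how the classes were drawn. Without that cluster 1092 genes were higher and 1915 lower, 642 and 1583 of them the same. The progenitor-like cells left still held the cluster led by Tesc, where 86.7% of cells had at least 3 G2 and M phase genes. Every list called lost its call with an estimated correlation. All 42 G2 and M phase genes were lower by either count (camera, adjusted p = 2.3e-25, adjusted p = 0.197 with an estimated correlation, and adjusted p = 4.6e-13 without the cluster led by histone genes), with Nusap1, a spindle protein, at 9.01 ± 0.489 CPM against 307 ± 13.7 CPM, and 22 of 30 S phase genes (adjusted p = 2.4e-08, and adjusted p = 0.272 with an estimated correlation). Wnt genes were lower in 16 of 31 cases, 18 adjusted over the list alone, and higher in 2 (adjusted p = 5.4e-05, and adjusted p = 0.127 with an estimated correlation), with Wnt7b at least 29.8-fold lower at 0 CPM against 7.06 ± 0.639 CPM. Notch genes were lower in 12 of 22 and higher in 1 by either count (adjusted p = 0.00686, and adjusted p = 0.197 with an estimated correlation), with Hes1, a Notch target, at 7.62 ± 1.26 CPM against 43.8 ± 13.5 CPM and Dll1, a Notch ligand, at 9.96 ± 2.25 CPM against 48.0 ± 5.64 CPM. Glial synapse-forming and pruning factors were lower in 11 of 23, 12 adjusted over the list alone (adjusted p = 0.0282, and adjusted p = 0.249 with an estimated correlation), with Gpc6, a glypican, at 0.550 ± 0.0817 CPM against 9.74 ± 2.16 CPM. Of the axon tract programme 6 of 18 genes were lower by either count (adjusted p = 0.0200, and adjusted p = 0.272 with an estimated correlation). Sodium and potassium channels were higher in 9 of 27, 10 adjusted over the list alone, and lower in 6 (adjusted p = 0.0290, and adjusted p = 0.197 with an estimated correlation). That list was not called with doublets kept (adjusted p = 0.213), with DESeq2 size factors (0.0621), without the low-count filter (0.0735), with all genes past the filter as background (0.0520) or without the cluster led by histone genes (0.217). Without clusters led by markers of another class, among them 984 and 1229 neuroblast-like cells, 675 genes were higher and 1447 lower, 618 and 1423 of them the same. With stricter quality limits Nusap1 had a log2 fold change of 0.060 (adjusted p = 0.902), and with 4000 variable genes -0.56 (adjusted p = 0.113).

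Each library may hold cells of male and of female mice, a hypothesis tested on barcodes with RNA of Xist, which females express, and of Y-linked genes. If sexes were pooled as separate cells, barcodes with both would be fewer than independent detection gives. Barcodes with both numbered 394 in library 1 and 667 in library 2, which were 0.235 and 0.418 of that expectation. Doublets and free RNA add such barcodes.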
